A study of Mus musculus with 24 samples.

How the data were processed

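DNA methylation was measured in 12 libraries of mouse iPS cells and embryoid bodies, from wild-type cells and the miR-203 knock-in clones N5 and N9 at 4 stages. Per the labels' protocols, the cells were grown over feeder cells in medium with 20% knockout serum replacement, and embryoid bodies were made by hanging drops. Per the same protocols, 200 ng of DNA were sheared to 800 bp, oxidised and bisulfite-converted with a TrueMethyl kit, amplified for 10 cycles and read as 125 bp pairs on a HiSeq instrument. The submitters' processing notes name BWA, Picard 1.91 and build mm10; the methylation caller is not given in the sources used here. The sample titles place 3 libraries (N5 at t=0, at day 25 and in embryoid bodies) on another flow cell than the other 9.

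The authors deposited a single table with 21875444 CpG positions and, for each library, counts of methylated calls and of all calls at a CpG. Per the file headers and values, the deposited methylated calls are whole-number counts with no normalization, and no methylated count exceeds its coverage. Per the file headers the deposited coverage columns of the wild type are counts of another layout, since each wild-type stage has 2 such columns. These were taken as the 2 lanes of a library and summed, because the sample titles of a stage share index and flow cell, though no header ties a column to a lane and the first column held fewer calls than the second at each stage. Were they separate libraries, the wild type would have n = 2 per stage. All 32 value columns were matched to libraries and 0 were left over. Of the CpGs, 2392630 had no call in any library, and 12915697 (59.0%) with calls in every library, on the assembled chromosomes, were used for levels. Mean coverage per CpG was 6.08, 5.97, 4.70 and 6.27 in the wild type at t=0, day 10, day 25 and in embryoid bodies, 5.42, 5.68, 8.74 and 5.65 in N5, and 5.91, 5.88, 5.57 and 6.18 in N9. Lanes are technical repeats, so n counts libraries.

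The plan was to use promoters around transcription start sites and CpG islands. The annotation at hand (RefSeq genes of GRCm38) gives gene starts and ends but no strand, and no genome sequence was used here, so neither could be placed. In their place, each of 21898 genes (21887 of them protein-coding) was given the window of 1000 bp on either side of the gene end that has more CpGs. For 71.9% of genes the denser end had more than 1.5 times the CpGs of the other. Some windows will therefore lie at the 3' end of a gene. CpG-rich ends have at least 60 CpGs in the window, dense CpGs at least 20 CpGs in 500 bp and sparse CpGs fewer than 10. Windows on chromosome Y and windows or tiles in the first 3000000 bp of a chromosome were left out.

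Methylation levels were pooled as methylated calls over all calls. Windows with at least 5 CpGs and 10 calls in every library (20329) and 248191 of 264937 tiles of 10000 bp with at least 30 calls in every library were tested. The test was the quasi-likelihood F test of edgeR 4.0.16 on methylated and unmethylated counts, with 8 groups of genotype and stage, 4 residual degrees of freedom and common dispersions of 0.024 for windows and 0.00581 for tiles. The single wild-type library of a stage is assumed to vary as the clones do. There were 10 comparisons: 3 between stages in the clones, 4 between clones and wild type at a stage, and 3 of the difference between clones and wild type in a change between stages. P values were adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. Changes are given in percentage points with their adjusted p, or in log2 odds where so named.

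The 13 gene lists (297 entries, all matched to symbols), the grouping, the comparisons, the tests and the alternatives were chosen before the data were examined, apart from those named as later. Of the lists, 11 of 21 genes for the 2-cell-like state and 15 of 16 trophoblast genes could be measured. Every gene of the other lists could be measured, among them 42 imprinted genes. Lists were tested with camera of limma 3.58.1 on the signed root of F, with a preset correlation of 0.01 between genes, adjusted over lists within a comparison. The test with an estimated correlation, adjusted in the same way, ran on limma logit values in place of the signed root of F. It thus differs in the statistic as well as in the correlation, and a lost call cannot be put down to correlation alone. Each list's median change was also placed among 10000 random lists matched for CpG number and level at t=0. Genes were named by a rule: in each direction the 10 largest changes in points among ends that passed with both clones moving the same way, for the 3 stage comparisons and the difference from t=0 to day 10, and the 5 largest for the rest. The rule adds the 4 members of each list with the lowest p, and Mir203, Dnmt3a, Dnmt3b, Pou5f1 and Nanog always. Other list members were named after their values were seen, because they passed.

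Unmethylated background was measured at 4500 CpG-rich ends under 5% in every library, a choice that limits how far it can move. It was 1.17% to 1.26% in the wild type, 1.31%, 0.989%, 0.682% and 1.66% in N5 at t=0, day 10, day 25 and in embryoid bodies, and 1.37%, 1.22%, 0.712% and 1.69% in N9. Mitochondrial CpGs were called methylated in 0.156% (N9 at day 25) to 0.649% (wild type at t=0) of calls. Noise between tiles, as chi-square per degree of freedom, was 1.66 to 1.72 between the wild-type columns of a library and 1.92 to 2.45 between clones. Differences between the clones were not shared across stages (Pearson r from -0.054 to 0.01 over 20329 ends, which are not independent replicates). The clones carry the same names at each stage, so a fit with the clone as a replicate block was run as an alternative. In that fit, with or without a flow cell term, comparisons with the wild type at a stage take the fitted level of N5. They do not take the mean of the clones. With the flow cell term this is the level of N5 as placed on the flow cell of N9. The term rests on the gap between N5 and N9 at day 10 against that at the other stages. Only at day 10 did the clones share a flow cell, so a departure of either day 10 library cannot be told apart from a flow cell effect. In comparisons between stages and in differences of change the clone term cancels.

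The tests were tried on simulated data with known changes, as if between t=0 and day 25 of the clones. With noise guessed beforehand, 0% of windows changed by 1 or 2 log2 odds passed by edgeR, with 42% and 88% at an unadjusted p under 0.05, and 0% by limma. Noise measured between the clones and larger changes were set after that outcome. With them edgeR recovered 0%, 38%, 82% and 92% of windows changed by 1, 2, 3 and 4 log2 odds, with 6 false calls, and limma 0%, 0%, 6% and 36%, with 1 false call. In 20000 tiles edgeR recovered 5% and 34% of changes of 0.5 and 1 log2 odds with noise guessed beforehand. With measured noise it recovered 18%, 70%, 94% and 100% of changes of 0.5, 1, 1.5 and 2 log2 odds, with 10 false calls. The simulated sets held 50 or 100 changed windows of each size, so they speak only for comparisons with few changed windows.

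The alternatives were limma on logit values with a pseudocount of 1, the same after centring each library on its median end, other coverage minimums (30 or 1 for windows, 100 for tiles, 5 for CpGs), windows of 2000 bp, autosomes alone, the replicate block with and without a flow cell term, means of per-CpG levels, an estimated correlation and leaving out each library in turn. After seeing the data, testing both gene ends, leaving out chromosomes 8 and X, and day 10 as the baseline in place of t=0 were added. Coverage of chromosomes was computed as calls per CpG relative to chromosome 5. CpG-rich X-linked ends, the ends of 3 measured of 5 listed genes known to escape X inactivation, and the start of chromosome Y were looked at for the number and state of sex chromosomes. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and data.table (1.17.8). Sequence-level analysis, expression data and hydroxymethylation were not analysed here.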

Results

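Oxidative bisulfite whole-genome sequencing, in which an oxidation step keeps 5-hydroxymethylcytosine from being read as 5-methylcytosine, was applied to mouse induced pluripotent stem (iPS) cells. Wild-type cells and 2 clones, N5 and N9, carrying a doxycycline-inducible knock-in of the microRNA miR-203 were sampled at 4 stages. Per the series design these were t=0, before doxycycline, then day 10, which fell 5 days after a doxycycline pulse of 5 days, then day 25, which fell 20 days after it, and last embryoid bodies at day 32. Embryoid bodies are aggregates in which pluripotent cells differentiate. The label of the wild-type embryoid bodies gives 10 days of aggregation where the design gives 7. The 24 deposited samples were 12 libraries run on 2 lanes each, so each stage had 1 wild-type library and 2 knock-in libraries, 1 per clone.

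The libraries held between 102896335 calls at CpGs (wild type, day 25) and 191210205 (N5, day 25). Mean coverage per CpG ranged from 4.70 in the wild type at day 25 to 8.74 in N5 at day 25. Of 21875444 CpGs of genome build mm10, 12917858 (59.1%) had calls in every library. Values of the knock-in cells are means with the SD of the 2 clones (n = 2). Values of the wild type come from 2 columns per stage, taken as lanes of a single library, and, where they are a share of calls, carry a 95% Wilson interval. These intervals cover counting error only. Gene values are the methylation of a window of 1000 bp on either side of the gene end with more CpGs, called a gene end here because the annotation used gives no strand.

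Methylation of all CpGs in the knock-in clones was 65.1% ± 0.039 at t=0, 60.6% ± 0.552 at day 10, 48.2% ± 0.511 at day 25 and 71.8% ± 0.556 in embryoid bodies (SD, n = 2). In the wild type, all CpGs together stood at 60.7% (95% interval 60.74 to 60.76) at t=0 and 61.5% (61.44 to 61.46) at day 10. The wild-type level was 61.2% (61.22 to 61.24) at day 25 and 69.7% (69.69 to 69.71) in embryoid bodies. From t=0 to day 10 the level changed by -4.90 percentage points in N5 and -4.17 in N9, against 0.704 in the wild type. From t=0 to day 25 it changed by -16.5 points in N5 and -17.2 in N9, against 0.486 in the wild type. From day 25 to embryoid bodies it changed by 23.6 points in N5 and 23.5 in N9, against 8.47 in the wild type. Embryoid bodies of the clones stood 6.71 ± 0.595 points above t=0, and the wild-type embryoid bodies 8.95 points. Each of these clone changes exceeded its SD between clones. With 2 clones a stage, a two-sided exact permutation test between stages cannot give p below 0.333, and the levels were not tested here in another way.

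The low level at day 25 ran through every class of CpG measured. Intergenic CpGs of the clones went from 70.4% ± 0.023 at t=0 to 53.5% ± 0.708 at day 25, gene bodies from 63.0% ± 0.093 to 45.9% ± 0.450, and CpG-poor gene ends from 42.1% ± 0.278 to 29.6% ± 0.369. CpG-rich gene ends, largely unmethylated at the outset, went from 5.26% ± 0.049 to 3.10% ± 0.020. In embryoid bodies the same 4 classes stood at 78.0% ± 0.535, 69.2% ± 1.14, 48.9% ± 1.09 and 6.76% ± 0.542. Chromosome X followed a different course at first, with a change from t=0 to day 10 of -1.69 ± 0.127 points against -4.61 ± 0.525 on the autosomes.

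**Figure D1:**
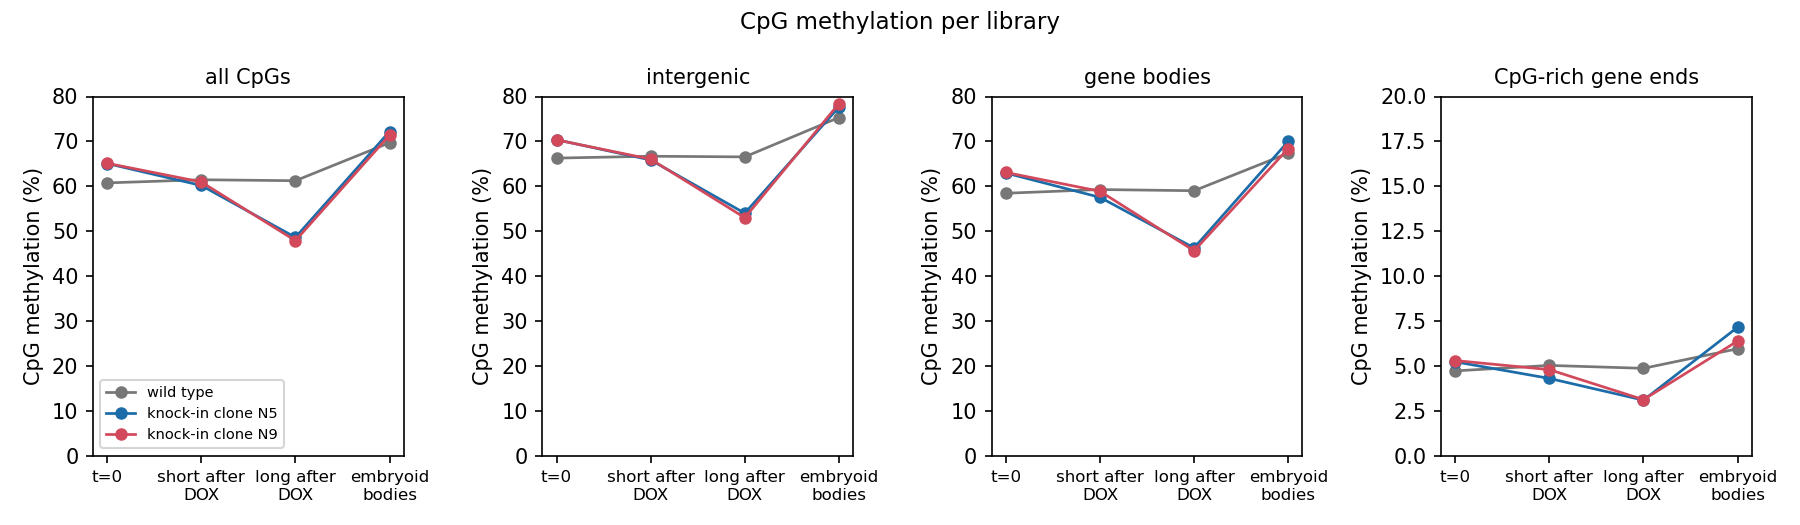
Methylation (%) of all CpGs, intergenic CpGs, gene bodies and CpG-rich gene ends in each library at t=0, short after doxycycline (day 10), long after it (day 25) and in embryoid bodies, for wild type (grey), N5 (blue) and N9 (red). Both clones sit near 48.2% over all CpGs at day 25, where the wild type stands at 61.2%.

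The comparison of the clones at t=0 and day 10 asks what a short episode of miR-203 expression left in the methylome 5 days after it ended. In the knock-in cells, 30 gene ends rose and all 30 lay on chromosome X, while 11 fell and 0 of those were X-linked (edgeR, 20329 ends tested, 777 of them X-linked). Magt1, a magnesium transporter gene, rose from 0.31% ± 0.43 to 6.56% ± 0.66 (adjusted p = 0.00494). The signalling ligand gene Eda, the lysosomal sulfatase gene Ids, the glypican gene Gpc3, the protocadherin gene Pcdh19, the histone demethylase gene Phf8, and Mid1ip1 and Ptchd1 rose by 5.27 to 6.79 points, with adjusted p from 0.00649 to 0.026.

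The 11 ends that fell by day 10 lay on autosomes, and their calls depended on the test. All 41 calls of this interval were kept with a coverage minimum of 30 calls and with none. With the clones as a block 9 ends were lower. A flow cell term beside the block gave 3 lower and 24 higher, and 17 of the 41 calls were shared. On autosomes alone 0 ends passed by edgeR, with 2193 at an unadjusted p under 0.05, with chromosomes 8 and X left out 0 passed, with 2085 unadjusted, and limma called 1 end lower. Lefty2, which encodes an antagonist of Nodal signalling (1, 180892108 to 180894108), fell from 34.8% ± 2.01 to 13.4% ± 4.86 (adjusted p = 0.0163). Ifng, the interferon gamma gene, fell from 70.3% ± 4.91 to 43.3% ± 1.52 (adjusted p = 0.0212), and the pro-apoptotic gene Bbc3 from 23.8% ± 6.80 to 6.87% ± 1.53 (adjusted p = 0.0135). The centrosome gene Nin, the scaffold gene Magi2, and Tmem40 and Krtap22-2 changed by -28.4 to -19.25 points; with the clones as a block Magi2 and Krtap22-2 had an adjusted p of 0.051. The odorant receptor gene Olfr1166 changed by -31.5 points, with an SD of 24.8 between the clones at t=0. Lpcat4 and Gm52523, whose windows overlap, changed by -2.31 and -1.75 points. Of the genes followed throughout, none passed from t=0 to day 10: Mir203 itself went from 13.9% ± 0.17 to 8.38% ± 1.52 (adjusted p = 0.407), Dnmt3a from 67.3% ± 1.13 to 62.6% ± 0.81 (0.755), Dnmt3b from 4.11% ± 1.55 to 3.96% ± 0.71 (0.987), Pou5f1 from 29.9% ± 1.86 to 27.8% ± 0.78 (0.899) and Nanog from 10.4% ± 0.52 to 10.48% ± 1.86 (0.999).

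The X-linked rise was broad. Of 286 CpG-rich X-linked ends, 244 were higher at day 10 than at t=0, with a median change of 2.41 points, while 3210 of 10628 CpG-rich autosomal ends were higher, with a median of -0.421. The median CpG-rich X-linked end stood at 3.34% in N5 and 3.52% in N9 at t=0, 5.85% and 6.37% at day 10, 1.496% and 1.769% at day 25, and 6.86% and 5.52% in embryoid bodies. In the wild type it stood at 8.51%, 9.81%, 8.92% and 6.69%. Coverage of chromosome X relative to the wild-type mean moved in the same interval, from 0.798 in N5 and 0.802 in N9 at t=0 to 1.07 and 1.06 at day 10. Coverage of the start of chromosome Y relative to chromosome 5 was 0.0389 and 0.0407 in the clones at t=0 and 0.0013 and 0.0009 at day 10.

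**Figure D2:**
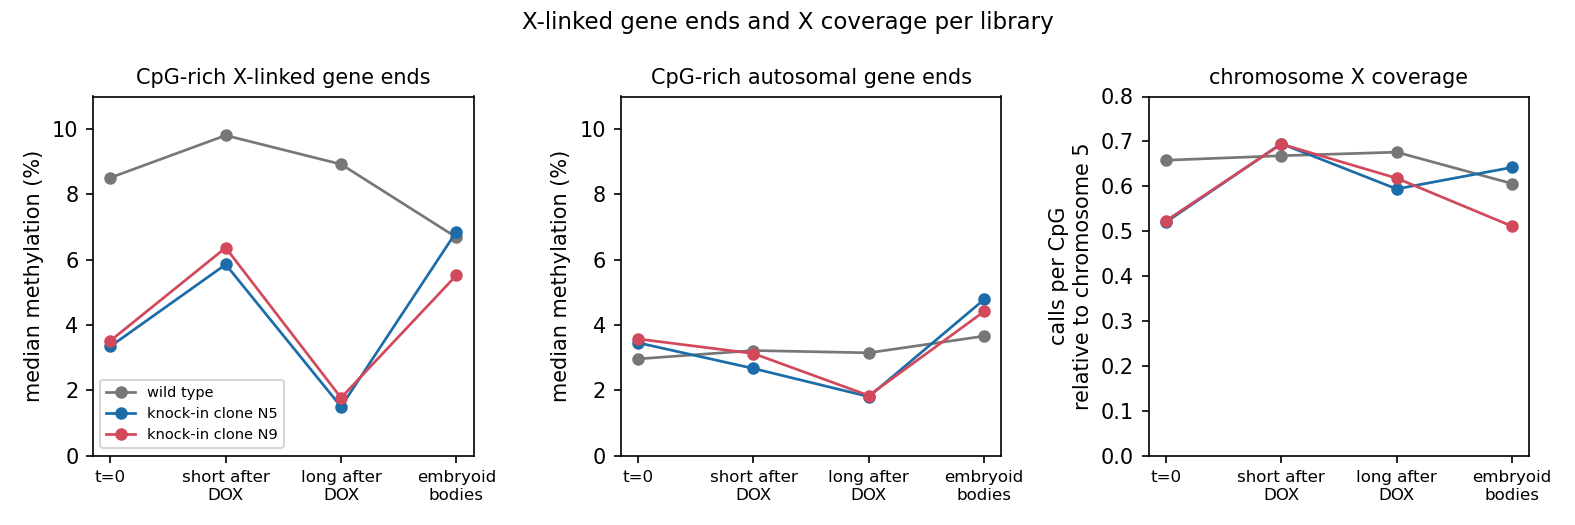
Median methylation (%) of 286 CpG-rich X-linked gene ends and of 10628 CpG-rich autosomal ends, and calls per CpG on chromosome X relative to chromosome 5, in each library by stage (wild type grey, N5 blue, N9 red). In the clones the X-linked median goes from 3.34% and 3.52% at t=0 to 5.85% and 6.37% at day 10, while the autosomal median does not rise.

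Across the genome, 24376 of 248191 tiles of 10 kb fell and 86 rose from t=0 to day 10 (edgeR), with a median change of -4.33 points, and 87.8% of tiles were lower. A tile at Triqk (4, 12930001 to 12940000) changed by -44.8 points (adjusted p = 6.84e-04), and one at Rtl8b (X, 53670001 to 53680000) by 22.2 points (adjusted p = 0.0141). By limma, 0 tiles passed, with 61652 at an unadjusted p under 0.05. Among the 13 gene lists none passed the list test, though in windows of 2000 bp Hox (adjusted p = 3.48e-05) and neuroectoderm genes (0.0225) did, and the Hox and fibroblast medians lay at percentiles 99.71 and 99.65 of the matched lists. The lowest adjusted p, 0.0609, was shared by the 18 neuroectoderm ends (0.44 with an estimated correlation) and the 39 Hox ends (0.499 with an estimated correlation). In both cases the test pointed to a smaller change than in other ends.

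The wild type, sampled across the same interval, sets the background for these changes. For 8 ends the change from t=0 to day 10 differed between the clones and the wild type, of which 7 were X-linked and higher in the clones. Fmr1, whose product is the RNA-binding protein lost in fragile X syndrome (X, 68677536 to 68679536), went from 0.38% ± 0.01 to 4.83% ± 0.21 in the clones. In the wild type it went from 7.97% (95% interval 6.34 to 9.98) to 3.52% (95% interval 2.31 to 5.32) (adjusted p for the difference = 0.0413). Txlng, the glycerol kinase gene Gk, the transcriptional coregulator gene Hcfc1, and Brcc3, Cmc4 and Mtcp1, whose windows overlap, differed by 3.82 to 9.40 points in the same direction. The exception was Tasor (14, 27482555 to 27484555), which encodes a component of a silencing complex and went from 76.8% ± 2.53 to 54.4% ± 6.17 in the clones and from 44.4% (95% interval 32.85 to 56.68) to 86.9% (95% interval 76.2 to 93.2) in the wild type. With the clones as a block, that is with N5 and N9 paired across stages, 0 of these 8 differences passed by edgeR. Adjusted p was 0.056 for Fmr1 and Txlng and 0.0579 for the other 6, and 1464 ends had an unadjusted p under 0.05. A flow cell term beside the block gave 9 differences by edgeR, 4 of them among these 8. Limma called 0. For tiles, 0 differences passed by edgeR, with 769 higher and 33772 lower at an unadjusted p under 0.05, and 0 by limma. Without N9 at day 10, 1492 tile differences passed by edgeR.

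The counts for this interval were small and moved with single libraries. Without N5 or N9 at t=0 the 41 ends that changed became 5 and 2, and without N5 at day 10 they became 20; limma called 9 higher and 1 lower. The 24462 tiles became 878 without N5 at t=0, 1290 without N9 at t=0 and 355 without N5 at day 10, and the 8 differences from the wild type became 0, 0 and 3 in the same order. After centring each library on its median end, limma called 13 ends higher and 1 lower. Testing both ends of each gene gave 31 higher and 58 lower.

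The comparison of t=0 with day 25 asks what remained 20 days after doxycycline. In the clones 8187 of 20329 gene ends fell and 3 rose (edgeR), with a median change of -3.91 points over all ends. Mir203 (12, 112129955 to 112131955) fell from 13.9% ± 0.17 to 6.03% ± 1.44 (adjusted p = 0.00838). Nanog, a core pluripotency factor gene (6, 122706489 to 122708489), fell from 10.4% ± 0.52 to 1.9% ± 1.59 (adjusted p = 8.07e-04). Of the genes for DNA methyltransferases, Dnmt1 fell from 77.0% ± 4.12 to 56.7% ± 5.01 (adjusted p = 0.00459) and Dnmt3a from 67.3% ± 1.13 to 50.8% ± 1.13 (adjusted p = 0.0168). Dnmt3b stood at 4.11% ± 1.55 and 2.11% ± 0.18 (adjusted p = 0.0806), and Pou5f1 at 29.9% ± 1.86 and 23.8% ± 4.66 (adjusted p = 0.28), so neither passed.

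Germline genes had the largest share of ends that fell among the lists, 24 of 28, and 24 adjusted over the list alone. Tdrd9, a gene of the piRNA pathway, fell from 73.5% ± 0.22 to 50.6% ± 3.67 (adjusted p = 0.0021), Tex13b from 88.0% ± 3.11 to 59.1% ± 0.99 (1.35e-04), Asz1 from 55.0% ± 5.77 to 35.02% ± 4.68 (0.00847) and the synaptonemal complex gene Sycp3 from 47.9% ± 6.51 to 31.2% ± 1.22 (0.0168). The list as a whole fell more than other ends (camera adjusted p = 2.32e-04, median -17.1 points). That call is lost with the correlation estimated from the data (adjusted p = 0.472 with an estimated correlation), and among random lists matched for CpG number and level at t=0 the median lay at percentile 11.42.

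Of 24 pluripotency ends, 14 fell, or 15 adjusted over the list alone. Tcl1 fell from 22.3% ± 8.62 to 4.48% ± 0.11 (adjusted p = 1.35e-04), Dppa3, a maternal-effect gene also known as Stella, from 15.4% ± 1.5 to 5.51% ± 2.95 (0.00459), and Tfcp2l1 from 4.19% ± 0.63 to 1.16% ± 0.49 (0.00773). Esrrb stood at 55.9% ± 1.46 and 42.2% ± 0.54 (0.0534). The list test did not pass (adjusted p = 0.076, 0.0324 with the clones as a block and 0.472 with an estimated correlation), while the list's median of -4.58 points lay at percentile 1.40 of 10000 random lists matched for CpG number and level at t=0. Of 42 imprinted ends 19 fell, or 20 adjusted over the list alone, among them Phlda2, a growth regulator of the placenta, from 4.39% ± 0.98 to 0.91% ± 0.13 (0.00189), Gnas from 7.17% ± 1.21 to 1.96% ± 1.01 (0.00242), Mirg from 43.1% ± 1.80 to 26.0% ± 5.26 (0.016) and Cdh15 from 52.1% ± 0.23 to 33.8% ± 2.02 (0.00929). The list test gave an adjusted p of 0.757 and the matched lists percentile 2.13. Of 20 methylation machinery ends 8 fell, also adjusted over the list alone, including Zfp57, which encodes a zinc finger protein that maintains imprints, from 41.2% ± 5.03 to 12.5% ± 3.95 (2.34e-04). Of 11 measured ends of genes of the 2-cell-like state 5 fell, or 7 adjusted over the list alone, including Spz1 and Usp17le. List tests for the machinery and the 2-cell-like genes gave an adjusted p of 0.693 for each.

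Lineage genes were part of the same fall. Of 39 Hox ends 14 fell, also adjusted over the list alone, including Hoxd4 from 31.9% ± 5.56 to 16.7% ± 5.81 (adjusted p = 0.0113), Hoxc4 from 43.7% ± 2.02 to 27.4% ± 0.12 (0.0164) and Hoxd12 from 14.3% ± 3.24 to 6.78% ± 0.86 (0.0171). Of 21 mesoderm and cardiac ends 10 fell, or 12 adjusted over the list alone, among them the sarcomere genes Tnnt2 and Myl7. Of 17 endoderm ends 8 fell, or 9 adjusted over the list alone, among them Ttr, encoding transthyretin, from 70.03% ± 5.02 to 41.0% ± 2.80 (5.78e-04), and Hnf4a, a liver transcription factor gene, from 68.6% ± 1.03 to 41.5% ± 2.19 (0.00113). Of 15 haematopoietic ends 8 fell, or 10 adjusted over the list alone, including Runx1 and Itga2b, and of 15 trophoblast ends 6 fell, also adjusted over the list alone, including Plet1 and Elf5. Of 15 housekeeping ends 4 fell, also adjusted over the list alone, including Actb. List tests gave adjusted p of 0.643 for Hox, 0.693 for mesoderm, 0.658 for endoderm, 0.451 for haematopoietic, 0.693 for trophoblast and 0.145 for housekeeping genes.

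Few neuroectoderm and fibroblast ends fell. Of 18 neuroectoderm ends 3 fell, or 0 adjusted over the list alone by edgeR, with small changes at Otx2, Pax3 and Tubb3, and of 20 fibroblast ends 3 fell, or 2 adjusted over the list alone, including S100a4 from 56.0% ± 4.52 to 40.3% ± 2.94 (adjusted p = 0.0287). The medians (-0.86 and -1.28 points) and means were negative. The list test was positive for both (camera adjusted p = 0.0308 and 0.0183), since their ends fell less than others. Neither call is kept by the test with an estimated correlation, which ran on logit values (camera adjusted p = 0.472 and 0.275). The correlation estimated for the fibroblast list, -0.037, lay below the preset 0.01, so correlation does not account for that loss. The fibroblast median lay at percentile 99.96 of the matched lists and the neuroectoderm median at 54.14, near the matched median of -0.89. Across all 10 comparisons, none of the 13 list calls made with the preset correlation was kept with an estimated one. Beside the fibroblast ends, coverage of the start of chromosome Y relative to chromosome 5 was 0.0129 in N5 and 0.011 in N9 at day 25, against 0.0389 and 0.0407 at t=0.

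**Figure D3:**
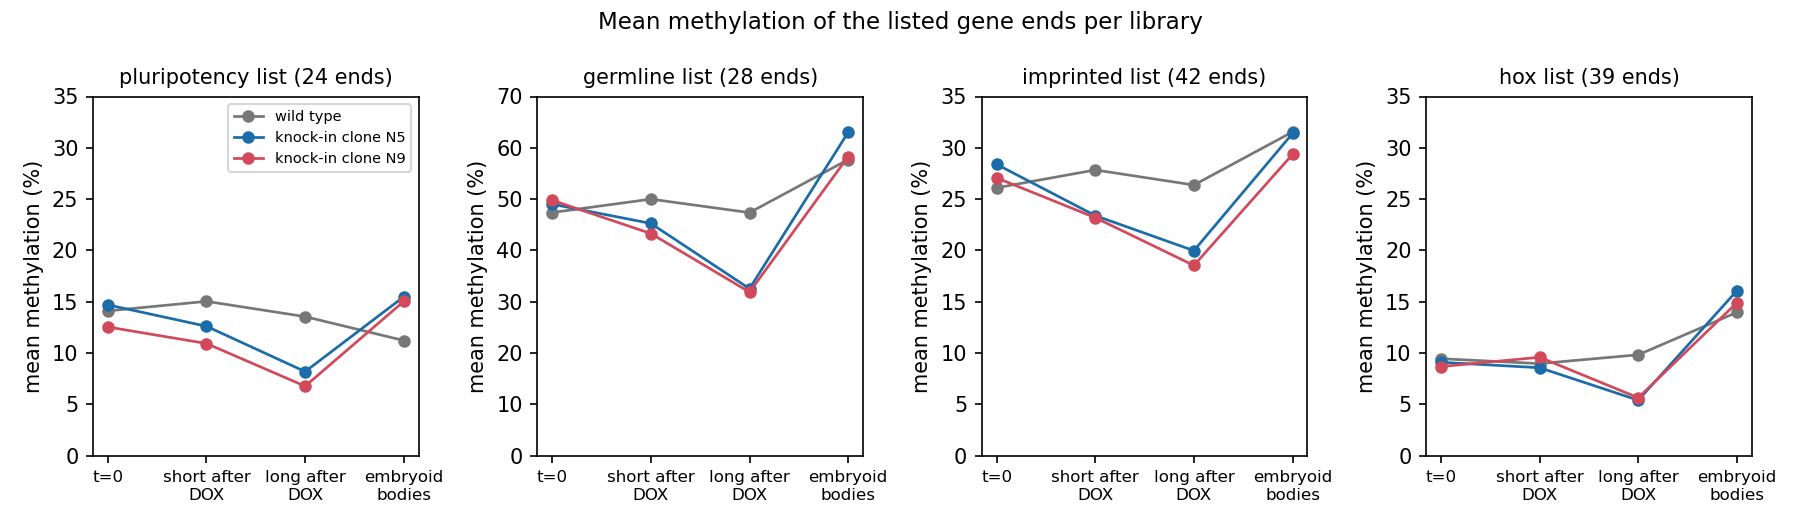
Mean methylation (%) of the measured ends of 24 pluripotency, 28 germline, 42 imprinted and 39 Hox genes in each library by stage (wild type grey, N5 blue, N9 red). In both clones each of the 4 lists is lowest at day 25.

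Among the largest falls at gene ends from t=0 to day 25 were 7 ends with few CpGs. The vomeronasal receptor gene Vmn2r23, the odorant receptor genes Olfr954, Olfr961 and Olfr1094, the natural killer cell receptor gene Klrk1, and Gm34733 and Gm47679 changed by -48.0 to -40.7 points. These 7 windows hold 6 to 13 CpGs and, in the library with the fewest calls, 10 to 25 calls. With more coverage, Msln, the mesothelin gene (17, 25753378 to 25755378), fell from 64.2% ± 1.3 to 23.0% ± 4.19 (adjusted p = 2.35e-04), Ceacam19 from 58.9% ± 7.68 to 17.7% ± 1.01 (9.9e-05) and the X-linked homeobox gene Rhox7a from 66.4% ± 4.08 to 25.3% ± 3.48 (8.69e-04). The 3 ends that rose were low in methylation: Hmgcs1, encoding an enzyme of cholesterol synthesis, from 1.21% ± 0.12 to 3.03% ± 0.02 (0.0463), Rbm4b from 0.00% to 0.90% ± 0.16 (0.0142) and Mnat1 from 0.15% ± 0.01 to 0.99% ± 0.94 (0.0196). In windows of 2000 bp on either side, the log2 odds change of Rbm4b was -0.93. Of the 10-kb tiles, 236131 of 248191 fell and 2 rose (edgeR; limma 236486 and 3), with a median change of -16.5 points.

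The change in the clones was tested against that in the wild type, whose level over all CpGs changed by 0.486 points. For 442 ends the change from t=0 to day 25 was lower in the clones than in the wild type and for 0 it was higher (edgeR, with 47 higher at an unadjusted p under 0.05). Limma called 0 in either direction, with 4585 at an unadjusted p under 0.05. Among these 442 were Dnmt1, at -37.7 points (adjusted p = 0.0278), Zfp57, at -31.3 points (0.0405), the meiotic gene Syce1, at -42.4 points (0.0162), the homeobox genes Hoxb5, at -9.7 points (0.0434), and Hoxc9, at -7.9 points (0.0394), the head patterning gene Otx2, at -9.6 points (0.0372), and the blood transcription factor gene Gata2, at -8.3 points (0.0479). The largest differences were at Klrk1, Pramel16, Olfr961, Septin11 and Skint2, at -93.0 to -59.8 points, where the thinnest library had 12 to 27 calls. Each difference also holds the change of the wild type at that end, from a single library per stage. At Dnmt1 the fall in the clones, given above, was smaller than the difference. At Klrk1 the clones changed by -45.4 points, and the wild type went from 44% at t=0 to 91.7% at day 25. With the clones as a block Septin11 had an adjusted p of 0.0506. For tiles, 167786 differences were lower and 8 higher in the clones (limma 156964 and 47), with a median of -16.7 points.

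In this comparison the counts of ends varied with single libraries more than the genome-wide level did. Without N5 or N9 at t=0 the 8190 ends became 4628 and 4373, and without N5 or N9 at day 25 they became 4160 and 4395; the 442 differences became 117, 130, 93 and 5 in that order. With day 10 in place of t=0 as the baseline, where Y coverage was near 0, 2102 ends fell and 3 rose, the differences from the wild type were 30 for ends and 73688 for tiles, and the level over all CpGs changed by -12.3 points. After centring each library on its median end, which takes away any change common to all ends, limma called 0 ends, with 1759 at an unadjusted p under 0.05.

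The comparison of day 25 with embryoid bodies asks how methylation changed on differentiation. In the clones 15207 of 20329 ends rose and 1 fell (edgeR), with a median change of 7.22 points, and 246587 of 248191 tiles rose and 0 fell (edgeR, 0 lower at an unadjusted p under 0.05; limma 246572 and 1), with a median of 23.9 points. Spic, a transcription factor gene of the Ets family (10, 88682023 to 88684023), rose from 18.4% ± 8.73 to 79.5% ± 3.76 (adjusted p = 4.17e-08), and Klf17, a Krüppel-like factor gene, from 20.3% ± 1.02 to 77.0% ± 4.72 (2e-08). The neuronal nitric oxide synthase gene Nos1 rose from 26.1% ± 2.72 to 81.7% ± 1.9 (1.28e-08), S100a14 from 27.9% ± 2.27 to 84.2% ± 0.10 (3.05e-09) and the interleukin receptor gene Il18r1 from 15.9% ± 5.62 to 70.9% ± 7.24 (2.78e-08). Gpr174, Olfr1094, Smr3a, Mylk4 and the cytochrome P450 gene Cyp2u1 rose by 54.0 to 57.3 points. The 1 end that fell, Mnat1, changed by -0.99 points, and in windows of 2000 bp its log2 odds change was 0.55. Mir203 rose to 15.9% ± 0.86 (6.42e-04), Dnmt3a to 78.4% ± 0.84 (2.46e-05), Dnmt3b to 6.07% ± 2.35 (0.00297) and Nanog to 11.6% ± 4.24 (3.32e-05), while Pou5f1 stood at 23.8% ± 4.66 and 32.4% ± 3.72 (0.102).

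Germline ends rose in 27 of 28 cases, or 28 adjusted over the list alone, and more than other ends (camera adjusted p = 4.54e-07, median 29.7 points; adjusted p = 0.251 with an estimated correlation). Sycp3 reached 70.6% ± 1.37 and Asz1 78.9% ± 8.11. Hox ends rose in 37 of 39 cases, or 38 adjusted over the list alone, with a median of 7.19 points at percentile 100 of the matched lists (camera adjusted p = 0.0332, and 0.251 with an estimated correlation). Hoxd4 reached 56.0% ± 0.99 and Hoxb6 rose from 5.46% ± 0.62 to 20.8% ± 0.85 (adjusted p = 1.03e-05). Trophoblast ends rose in 13 of 15 cases, also adjusted over the list alone, with a median of 28.5 points (camera adjusted p = 0.0332, and 0.251 with an estimated correlation). Among them the homeobox gene Esx1 rose from 18.4% ± 8.38 to 60.8% ± 9.73 (7.51e-07), Gata3 from 15.2% ± 1.68 to 45.0% ± 2.25 (5.27e-06) and Plet1 from 12.2% ± 1.48 to 43.2% ± 6.54 (1.97e-06).

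Of the other lists, 20 of 21 mesoderm ends rose, with Tnnt2 at 77.4% ± 0.14 and the heart transcription factor gene Tbx5 at 67.6% ± 2.90, as did 15 of 17 endoderm ends, with Ttr at 81.8% ± 2.36 and Foxa1 at 24.5% ± 0.90. Neuroectoderm ends rose in 15 of 18 cases (16 adjusted over the list alone), with Pax6, an eye and brain patterning gene, going from 1.81% ± 1.16 to 8.75% ± 2.52 (adjusted p = 7.94e-05). Rises were also called for 17 of 20 fibroblast ends (18 adjusted over the list alone), 12 of 15 haematopoietic ends (13), 16 of 24 pluripotency ends (16), 14 of 20 machinery ends (14), 29 of 42 imprinted ends (29), 9 of 11 ends of 2-cell-like genes (9) and 6 of 15 housekeeping ends (5). List tests for these groups did not pass, with adjusted p of 0.0808 for mesoderm, 0.1 for endoderm, 0.921 for neuroectoderm, 0.442 for fibroblast, 0.115 for haematopoietic, 0.931 for pluripotency, 0.705 for machinery, 0.162 for imprinted, 0.968 for 2-cell-like and 0.0753 for housekeeping genes. Among the matched lists the fibroblast median lay at percentile 99.6 and the neuroectoderm median at 96.53. The tests for neuroectoderm, machinery, imprinted, 2-cell-like and housekeeping genes were negative while their medians and means were positive.

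Wild-type cells also gained methylation in embryoid bodies, so the gain in the clones was tested against it. Genotype is not the only difference here, since the labels give doxycycline for the embryoid bodies of the clones and not for those of the wild type, and 10 days of differentiation for the wild type where the design gives 7. By edgeR the change was higher in the clones than in the wild type at 1279 ends and lower at 4 (limma 188 and 0). Among tiles it was higher at 152321 and lower at 37 (limma 140149 and 65). Of these 1279 ends 212 were X-linked. Of 24 pluripotency ends 8 rose more in the clones, or 13 adjusted over the list alone (camera adjusted p = 1.44e-04; adjusted p = 0.245 with an estimated correlation). Nanog rose by 9.69 points in the clones and stood in the wild type at 12.2% (95% interval 8.75 to 16.67) at day 25 and 2.43% (95% interval 1.24 to 4.72) in embryoid bodies (adjusted p for the difference = 6.77e-04). Dppa4 differed by 41.5 points (1.58e-04), Dppa3 by 32.4 (0.00169), Dppa5a by 26.5 (0.0266), Pou5f1 by 19.9 (0.0484), Tcl1 by 18.1 (0.0237), Nr0b1 by 9.6 (0.0368) and Sall4 by 4.0 (0.0124). These differences also hold the change of the wild type at each end, which for Nanog was a fall.

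Germline ends rose more in the clones in 5 of 28 cases, or 13 adjusted over the list alone (camera adjusted p = 0.0269; adjusted p = 0.66 with an estimated correlation), namely Taf7l, Tdrd1, Asz1, Tdrd9 and Syce1, by 34.2 to 53.2 points. Hox ends did so in 7 of 39 cases (9 adjusted over the list alone), machinery ends in 5 of 20 (5), including Dnmt1, by 31.8 points (0.0213), and Zfp57, by 41.6 points (0.00407), and trophoblast ends in 2 of 15 (3), Plet1, by 45.2 points (7.99e-04), and Tfap2c, by 15.0 points (0.0383). Of the imprinted ends 4 differed upwards (Gnas, Magel2, Mkrn3 and Phlda2) and 1 downwards (Peg10, at -19.4 points, adjusted p = 0.0395), or 6 and 2 adjusted over the list alone. For fibroblast genes 0 of 20 ends differed by edgeR, also adjusted over the list alone. Yet the list test was negative (camera adjusted p = 1.44e-04, and 0.114 with an estimated correlation). The list had a median of 0.34 and a mean of -1.09 points against a median of 4.14 for all ends. Over this interval, coverage of the start of chromosome Y relative to chromosome 5 went from 0.0129 to 0.0009 in N5. It went from 0.011 to 0.0002 in N9 and from 0.0016 to 0.0007 in the wild type. The other ends with a lower change in the clones than in the wild type were Ccna2, a cyclin gene, Lor, and H2-T23. The log2 odds difference of H2-T23 was -3.71 and, in windows of 2000 bp, 0.08. Gpr174, Cdh19, Olfr1320, Klrk1 and Olfr1313 differed by 62.5 to 80.6 points, with 12 to 23 calls in their thinnest library. Without N5 or N9 at day 25 the 1283 differences became 712 and 680, and without N5 in embryoid bodies 664. Centred limma values gave 0 ends for the rise in the clones, with 3227 at an unadjusted p under 0.05, and 9 for the difference from the wild type.

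Set against the wild type at each stage, the clones differed at 113 ends at t=0, 5 at day 10, 2130 at day 25 and 19 in embryoid bodies (edgeR; limma 4, 0, 561 and 2). At t=0, 25 ends were higher in the clones, 0 of them X-linked, and 88 lower, 85 of them X-linked. With a flow cell term beside the clone block 0 were higher by edgeR and 32 lower, with 1398 at an unadjusted p under 0.05. None of the higher ends named here passed in that fit. In the fits with a clone block, comparisons with the wild type at a stage take the fitted level of N5, not the clones' mean. H19, a maternally expressed imprinted gene (7, 142577146 to 142579146), stood at 71.1% ± 2.15 in the clones and 37.2% (95% interval 31.88 to 42.94) in the wild type (adjusted p = 0.0118). Tmem40, Gm37116, Gm52051 and Gm7030 were higher by 31.9 to 37.9 points. Eda2r, a receptor gene, Hdx, Zfp36l3 and LOC115489115 on X and Fam169a on 13 differed by -21.5 to -18.0 points. With the clones as a block Gm52051 (adjusted p = 0.0689), Gm7030 (0.0765) and Zfp36l3 (0.0753) did not pass. The housekeeping gene Pgk1, on X, stood at 0.48% ± 0.20 against 6.27% (95% interval 4.72 to 8.28) (0.00461). On autosomes alone 0 ends differed by edgeR, with 1638 at an unadjusted p under 0.05.

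At day 10 the 5 ends were lower in the clones. Zdbf2, an imprinted gene (1, 63199358 to 63201358), stood at 18.4% ± 9.20 against 57.8% (95% interval 52.29 to 63.17) (adjusted p = 0.0374), H2ac1, a histone gene, at 20.6% ± 6.60 against 56.1% (95% interval 49.1 to 62.79) (0.0383), and the X-linked genes Rbmx2, Rps6ka3, a ribosomal S6 kinase gene, and Prps2 differed by -14.7 to -12.2 points. With the clones as a block 0 of these passed by edgeR, with 1467 at an unadjusted p under 0.05, and limma called 0. The block fit compares the fitted level of N5, not the clones' mean, with the wild type. Fibroblast ends as a list were higher than others (camera adjusted p = 0.0425, and 0.0508 with the clones as a block; adjusted p = 0.465 with an estimated correlation), though 0 of 20 passed by edgeR, also adjusted over the list alone.

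At day 25 the clones were lower at 2119 ends and higher at 11, and 341 of the lower ends were X-linked. With a flow cell term beside the clone block 804 were lower and 4 higher, 581 of them shared with the 2130. The block alone compares the fitted level of N5 with the wild type, and the fit with the flow cell term that level as placed on the flow cell of N9. Pluripotency ends were lower in 8 of 24 cases (10 adjusted over the list alone), including Dppa4, at -28.1 points (adjusted p = 2.83e-04), Dppa5a, at -24.9 (0.00188), and Nanog, at 1.9% ± 1.59 against 12.2% (95% interval 8.75 to 16.67) (0.00349). Germline ends were lower in 8 of 28 (15 adjusted over the list alone; camera adjusted p = 0.00332, and adjusted p = 0.771 with an estimated correlation), including Asz1, at -33.0 points (0.00332). Hox ends were lower in 8 of 39 (10 adjusted over the list alone), with Hoxd4 at 16.7% ± 5.81 against 52.0% (95% interval 45.48 to 58.49) (6.23e-04), and machinery ends in 6 of 20 (7 adjusted over the list alone), with Dnmt1 at 56.7% ± 5.01 against 85.3% (95% interval 79.19 to 89.84) (0.0036). Higher ends included H19, Vcam1, a vascular adhesion gene, Eif3j2, Gm52008 and the fibroblast list's Pdgfrb, a growth factor receptor gene, at 34.8% ± 2.82 against 16.9% (95% interval 12.78 to 22.1) (0.0385). With the clones as a block Eif3j2 (adjusted p = 0.062), Vcam1 (0.0877) and Gm52008 (0.0695) did not pass. A further fibroblast gene, Col1a1, was higher by 17.8 points (0.0112), and the list test was positive (camera adjusted p = 0.00332; adjusted p = 0.237 with an estimated correlation), with a median of -1.48 and a mean of 0.58 points. Coverage of the start of chromosome Y relative to chromosome 5 was 0.0129 and 0.011 in these clone libraries and 0.0016 in the wild type. The largest differences, at Olfr1094, Gpr174, Klrk1, Sult2a4 and Mia2, were -57.1 to -48.5 points.

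In embryoid bodies, which the labels set apart in doxycycline and days of differentiation as well, 13 ends were higher and 6 lower in the clones. Pou5f1, the gene of the pluripotency factor Oct4 (17, 35505032 to 35507032), stood at 32.4% ± 3.72 against 7.69% (95% interval 5.41 to 10.83) (adjusted p = 0.0134), the 1 pluripotency end of 24 to pass, with 8 higher adjusted over the list alone. The list was higher than other ends (camera adjusted p = 1.61e-04; adjusted p = 0.312 with an estimated correlation). Arl14epl stood at 81.9% ± 7.05 against 26.1% (95% interval 20.55 to 32.55) (2.8e-05), and Gm50595, Gm37116, the cardiac calcium-binding gene Casq2 and Tspoap1 were higher by 37.2 to 37.9 points. Lower ends included AY761185, Ccnb1ip1 and Rhox13, at -43.4 to -28.5 points, and the imprinted genes Kcnq1ot1 and Snurf, neither of which passed with a flow cell term beside the clone block. With the clones as a block 12 ends differed, and Gm37116 (adjusted p = 0.113), Tspoap1 (0.0525), AY761185 (0.0653) and Rhox13 (0.102) did not pass. A flow cell term beside the block left 4 ends, 3 higher and 1 lower, with 3 shared with the 19 of the main test. Both fits compare the fitted level of N5 with the wild type, the second as placed on the flow cell of N9. Leaving out N5 or N9 changed the counts at each stage: to 34 and 39 at t=0, 2 and 23 at day 10, 996 and 898 at day 25, and 6 and 8 in embryoid bodies. Each of these comparisons rests on 1 wild-type library, assumed to vary as the clones do.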

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

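The tests of the fall to day 25 (feeder cells, conversion, wild-type change), the test of conversion for the change to day 10 and the comparison of X-linked with autosomal ends were chosen only after the result was seen, as was the use of day 10 as a baseline; the other tests were set beforehand. The wild type has a single library per stage in each of them.

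Between the clones and the wild type, the change from t=0 to day 10 differed at 8 gene ends, from t=0 to day 25 at 442 ends and 167794 tiles, and from day 25 to embryoid bodies at 1283 ends and 152358 tiles, each by the edgeR test of the difference itself. Coverage of the start of chromosome Y relative to chromosome 5, which no comparison used, was 0.0389 in N5 and 0.0407 in N9 at t=0 and 0.0129 and 0.011 at day 25, above every wild-type library. Coverage of chromosome 8 relative to the wild-type mean was above the wild-type range in every knock-in library. It was 1.321 in N5 and 1.325 in N9 at t=0, 1.087 and 1.33 at day 10, 1.338 and 1.349 at day 25, and 1.342 and 1.174 in embryoid bodies.

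From t=0 to day 10 the level over all CpGs changed by -4.53 points in the clones. The values argue against several technical accounts of the whole change. N9, whose 4 libraries share a flow cell, changed by -4.171 points, and the change was -4.572 after thinning all libraries to equal calls. Unconverted calls would add most at CpG-rich autosomal ends. Their median at t=0, 3.45% in N5 and 3.57% in N9, was already smaller than the change over all CpGs, and this level argues against incomplete conversion. It changed by -0.421 (quartiles -1.452 and 0.109). The wild type, kept as long and given doxycycline, changed by 0.704. It differed from the clones in X-linked ends and chromosome 8 coverage, so it argues against culture time or doxycycline only for cells like itself. The number of X chromosomes cannot be told apart from the change, because the ratio of X to autosome coverage moved by 0.209 or more in both clones, between the bounds set beforehand for and against it. Y coverage was present at t=0 and near 0 at day 10, and chromosome 8 of N5 was lower at day 10 than before and after, so a different share of other cells, possibly feeder cells or cells of another line, stays open for part of the change, as does whether the libraries of a clone hold the same cells. An effect of miR-203 that outlasts doxycycline, the biological explanation the design names, may account for the rest and was not tested apart from these.

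From t=0 to day 25 the level changed by -16.9 points. Incomplete conversion is argued against as the cause by the CpG-rich autosomal ends. Their median at t=0, 3.45% in N5 and 3.57% in N9, was too low for such a fall, and it changed by -1.465 (quartiles -3.199 and -0.494). The wild type changed by 0.486 and its 3 iPS libraries lay between 60.7% and 61.5%. This argues against culture time or doxycycline alone only for cells like the wild type. At t=0 its median X-linked end stood at 8.51%, and chromosome 8 coverage of the clones at 1.321 and 1.325 of the wild-type mean. An effect of culture time on cells in the state of the clones was not tested. Fewer feeder cells cannot be told apart from the fall. A feeder share was expected beforehand to show as methylated Pou5f1 and Nanog ends. From t=0 to day 25 Nanog fell and Pou5f1 did not pass. Neither passed from t=0 to day 10, where Y coverage was near 0, so these ends do not decide it. Y over X coverage at t=0, averaged over the clones, was 7.63%, and the median tile would need 37.9% of fully methylated cells. These are unlike measures, since the coverage ratio is not a share of cells and no library known to be male calibrates it. Y coverage also shows male cells only. The bound for excluding female feeders (X-linked ends under 2%) was set too low to decide. At t=0 autosomal ends stood at 3.45% and 3.57%, and X-linked ends, at 3.34% and 3.52%, showed no excess over them. The 20 fibroblast ends, with no filter on level, had a median ratio of t=0 to day 25 of 1.157. All ends over 5% at day 25 had a median of 1.384, so these ratios are not on like sets. With day 10 as the baseline, where Y coverage in the clones was at most 0.0013, the level over all CpGs still changed by -12.32 points. Coverage of X and methylation of X-linked ends moved too, so a change in active X chromosomes and a lasting effect of miR-203 both stay open as hypotheses.

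From t=0 to day 10 CpG-rich X-linked ends rose in the clones, by a median of 2.41 points. A rise at CpG-rich ends of every chromosome is argued against by the autosomal ends, whose median change was -0.421. A candidate explanation is a larger share of cells with an inactive X at day 10: the ends of genes known to escape inactivation changed by a median of -0.447, on 3 genes only (Ddx3x, Eif2s3x and Kdm5c). The rise of X coverage from 0.798 and 0.802 of the wild type to 1.07 and 1.06 is consistent with it. Whether miR-203, or a shift between cells of different X content in culture, lies behind such a change was not tested.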

How the results depend on the processing

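Testing both gene ends, leaving out chromosomes 8 and X, and taking day 10 as the baseline in place of t=0 were chosen only after the data were seen; the other alternatives were planned. Counts below are of gene ends unless tiles are named, and the cause of a change was not tested unless the alternative's construction shows it. Among the results that answer a comparison, 556 alternatives gave a value on the same side of the threshold or within the bounds set, 112 moved a count or level, 17 ended a call, 15 made one and 1 turned a direction. Among single named genes and chromosomes these numbers were 849, 50, 470, 0 and 3. The fall to day 25 and the rise in embryoid bodies passed in at least 5802 ends under every alternative that kept t=0 and every library, except after centring, which takes a shared change away by construction. In simulated data for 2 clones against 2 clones with few changed windows, changes of 1 log2 odds in a window were not recovered; this does not bound the comparison of t=0 with day 25, where many ends changed.

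By limma, 10 ends changed from t=0 to day 10 in the clones. For the clones against the wild type limma called 4, 0, 561 and 2 from t=0 to embryoid bodies (1416 at an unadjusted p under 0.05 for the 0), and for the differences in change 0, 0 and 188 (1328 and 4585 for the 0 counts). It called 0 tiles from t=0 to day 10, with 61652 at an unadjusted p under 0.05. After centring, limma called 14, 0 and 0 for the 3 changes in the clones (1759 and 3227 unadjusted for the 0 counts), 5, 0, 14 and 2 against the wild type (1328 for the 0), and 0, 0 and 9 for the differences (1064 and 1352). The main counts by edgeR were 41, 8190 and 15208 for the changes, 113, 5, 2130 and 19 against the wild type, and 8, 442 and 1283 for the differences.

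Windows of 2000 bp gave 6 and 13816 ends for the changes to day 10 and day 25, 40, 5170 and 31 against the wild type at t=0, day 25 and in embryoid bodies, and 1, 3178 and 3005 for the differences. In them the log2 odds of 3 named genes turned: Rbm4b to -0.93 for t=0 to day 25, Mnat1 to 0.55 for day 25 to embryoid bodies and H2-T23 to 0.081 for the difference in that change. On autosomes alone edgeR called 0 ends from t=0 to day 10 (2193 at an unadjusted p under 0.05), 0 against the wild type at t=0 (1638), 1 at day 10 and 0 for the difference to day 10 (1349); with chromosomes 8 and X left out these were 0 (2085), 0 (1538), 1 and 0 (1286). The X-linked ends are absent from both by construction. A coverage minimum of 30 calls, or none, gave 14 ends against the wild type at day 10.

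Testing both ends gave 89 ends from t=0 to day 10, 31 higher and 58 lower, where the main test gave 30 higher and 11 lower. It gave 23987 and 33772 for the later changes, 15, 7101 and 32 against the wild type at day 10, day 25 and in embryoid bodies, and 0 (3228 at an unadjusted p under 0.05), 4365 and 3817 for the differences, by edgeR. With day 10 as the baseline, 2105 ends changed to day 25, 30 ends and 73688 tiles differed in change, and the level over all CpGs changed by -12.32 points.

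With the clone as a replicate block, edgeR called 0 ends against the wild type at day 10 (1467 at an unadjusted p under 0.05), 12 in embryoid bodies and 0 for the difference to day 10 (1464), the fibroblast list at day 10 went to an adjusted p of 0.0508 and the pluripotency list from t=0 to day 25 to 0.0324. The block also ended the calls of 26 named genes, given in the report, and changed no other list call. The other counts stayed within 1.5-fold, but the ends called were not all the same. Against the wild type 88 of 113 calls at t=0 and 1741 of 2130 at day 25 were shared. For the difference to day 25, 373 of 442 were shared. The block with a flow cell term gave 27 ends from t=0 to day 10, and 32, 30, 808 and 4 against the wild type. It gave 9 for the difference to day 10 and 1095 for that to day 25. In both fits, comparisons with the wild type at a stage take the fitted level of N5, not the clones' mean. With the flow cell term this level is placed on the flow cell of N9. The term rests on the day 10 libraries, so its counts do not separate a flow cell effect from a departure of those libraries.

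Leaving out a library leaves 1 in an arm, and that lone library is assumed to vary like the others. The counts of ends then ranged from 2 to 50, 4160 to 4628 and 11745 to 13071 for the changes, 34 to 39, 2 to 23, 898 to 996 and 6 to 8 against the wild type, and 0 to 9, 5 to 130 and 664 to 877 for the differences. Tiles ranged from 355 to 20505, 219284 to 222825 and 242716 to 244227 for the changes, and 0 to 1492, 147136 to 154588 and 126523 to 147929 for the differences. In single clones the change over all CpGs ranged from -4.896 to -4.171, -17.242 to -16.464 and 23.532 to 23.595 points in the 3 intervals. It ranged from -0.926 to -0.506, -2.178 to -2.138 and 3.266 to 4.062 at CpG-rich ends, -4.33 to -3.331, -12.553 to -12.425 and 18.754 to 19.771 at CpG-poor ends, and -5.422 to -4.196, -17.456 to -16.688 and 22.788 to 23.761 in gene bodies. It ranged from -4.519 to -4.298, -17.347 to -16.379 and 23.662 to 25.419 between genes, -1.332 to -0.76, -2.58 to -2.573 and 3.509 to 4.587 at dense CpGs, and -5.276 to -4.455, -18.244 to -17.102 and 24.407 to 26 at sparse CpGs. On X it ranged from -1.78 to -1.6, -15.294 to -14.825 and 22.604 to 23.374, and on autosomes from -4.978 to -4.235, -17.287 to -16.502 and 23.554 to 23.601.

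As means of per-CpG levels, the change from t=0 to day 25 was -16.188 points over all CpGs, -1.822 at CpG-rich ends, -12.317 at CpG-poor ends, -16.344 in gene bodies, -2.839 at dense CpGs, -14.452 on X and -16.242 on autosomes. From day 25 to embryoid bodies it was 23.353 over all CpGs, 5.025 at dense CpGs and 23.377 on autosomes, and on X from t=0 to day 10 -2.162. With CpGs of 5 or more calls, the change to day 10 was -1.03 at CpG-rich ends and -1.83 on X, that to day 25 -2.738 at CpG-rich ends, -12.115 at CpG-poor ends and -2.192 at dense CpGs, and that to embryoid bodies 24.082 over all CpGs, 4.718 at CpG-rich ends, 24.039 in gene bodies, 23.627 on X and 24.091 on autosomes. Autosomes alone gave -12.602 at CpG-poor ends and -2.584 at dense CpGs for t=0 to day 25.

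The list test with an estimated correlation also changed the statistic, from the signed root of F to limma logit values. With it, list calls ended from t=0 to day 25 for germline (adjusted p = 0.472), neuroectoderm (0.472) and fibroblast genes (0.275), and from day 25 to embryoid bodies for germline, trophoblast and Hox genes (0.251 each). Against the wild type they ended for fibroblast genes at day 10 (0.465) and day 25 (0.237), germline genes at day 25 (0.771) and pluripotency genes in embryoid bodies (0.312), and for the difference to embryoid bodies for pluripotency (0.245), germline (0.66) and fibroblast genes (0.114). Windows of 2000 bp ended the calls of neuroectoderm (0.0688) and fibroblast genes (0.0573) to day 25 and of trophoblast genes (0.0735) to embryoid bodies. They made calls for neuroectoderm (0.0225) and Hox genes (3.48e-05) to day 10, pluripotency genes (0.00189) to day 25, and mesoderm (0.02), endoderm (0.0197) and housekeeping genes (0.0197) to embryoid bodies. Against the wild type they did so for pluripotency and Hox genes at t=0 (0.0436 each), pluripotency, germline and imprinted (0.0176 each) and neuroectoderm genes (0.0267) at day 10 and pluripotency genes at day 25 (0.00164), and for the difference to day 10 for Hox genes (0.00782).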

Other observations

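The imprinted list was set beforehand, while the genes named from it here were chosen after their values were seen. Of 42 imprinted ends, 3 passed against the wild type at more than 1 stage: Kcnq1ot1, Snurf and H19. Kcnq1ot1, the gene of a paternally expressed antisense RNA (7, 143295547 to 143297547), was at 24.6% ± 10.6, 18.8% ± 7.84, 10.9% ± 2.42 and 19.8% ± 5.92 in the clones from t=0 to embryoid bodies (SD, n = 2). In the wild type it was at 45.5% (95% interval 41.23 to 49.9), 52.3% (95% interval 47.82 to 56.78), 52.4% (95% interval 47.04 to 57.78) and 64.7% (95% interval 59.57 to 69.59), and the difference passed at day 25 (edgeR adjusted p = 2.24e-04) and in embryoid bodies (0.0101). Snurf, whose gene lies in the Prader-Willi region (7, 60004199 to 60006199), was at 19% ± 11.25, 17.7% ± 5.20, 20.4% ± 5.70 and 18.9% ± 7.28 in the clones. The wild type stood at 38.3% (95% interval 31.77 to 45.37), 49.3% (95% interval 43.58 to 55.05), 61.3% (95% interval 53.84 to 68.21) and 58.1% (95% interval 50.62 to 65.13), with a difference that passed at day 25 (9.23e-04) and in embryoid bodies (0.0197).

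H19 went the other way, with 71.1% ± 2.15, 74.7% ± 6.03, 65.3% ± 0.82 and 83.3% ± 6.41 in the clones against 37.2% (95% interval 31.88 to 42.94), 42.3% (95% interval 36.88 to 47.9), 33.7% (95% interval 28.12 to 39.86) and 50.2% (95% interval 44.79 to 55.5) in the wild type. The difference passed at t=0 (edgeR adjusted p = 0.0118), day 25 (0.00527) and in embryoid bodies (0.013), and was 0.0529 at day 10. With a flow cell term beside the clone block, the calls of H19 at t=0 and of Kcnq1ot1 and Snurf in embryoid bodies were lost. That fit compares N5, as placed on the flow cell of N9, with the wild type and not the clones' mean. Its flow cell term rests on the day 10 libraries, so these losses cannot be put down to the flow cell. Igf2r, Airn, Magel2, Mkrn3 and Phlda2 were lower in the clones at day 25 (adjusted p from 0.0138 to 0.048). By limma, the adjusted p in embryoid bodies was 0.248 for Kcnq1ot1 and 0.363 for Snurf, and for H19 it was 0.298 at t=0. The list as a whole did not pass at any of the 4 stages, with camera adjusted p of 0.771, 0.0764, 0.906 and 0.164, but in windows of 2000 bp it did at day 10 (0.0176).

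In embryoid bodies of N5, coverage of chromosome 19 relative to chromosome 5 was 1.141, and in the other 11 libraries 1.058 to 1.071. In embryoid bodies of N9, coverage of X relative to the wild-type mean was 0.784, and in those of N5 0.985. Mean methylation of the 28 germline ends in embryoid bodies was 63.0% in N5, 58.3% in N9 and 57.7% in the wild type, and that of the 11 ends of 2-cell-like genes 85.8%, 86.1% and 79.1%.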
